A study of Mus musculus with 8 samples.

How the data were processed

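Whole cerebellum from 8 mice was profiled by RNA sequencing of bulk tissue. Per the series design, 4 mice were bigenic: they carried the CalExflox allele, from which a plasma membrane calcium pump is expressed after Cre recombination, together with Aldh1l1-Cre/ERT2, a tamoxifen-activated Cre recombinase expressed in astrocytes. The other 4 mice carried CalExflox without Cre and served as controls. All 8 mice received tamoxifen at 75 mg/kg by intraperitoneal injection, prepared at 25 mg/ml in corn oil, and tissue was taken 5 days later. The labels give each sample a mouse of its own, so the replicates are separate animals. They give neither the sex, the age nor the time of day at collection. Because the bigenic mice alone carry Cre, the effect of the pump and the effect of Cre itself are not separable in this design. Striatal tissue named in the series design was not analysed here.

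The labels disagree on the library preparation. The series design names a mirVana extraction, Nugen Ovation libraries and a NextSeq instrument, whereas the sample protocols name a Qiagen column kit, stranded TruSeq libraries with ribosomal RNA removal and a HiSeq4000. Per the series design, RNA had an integrity number above 7 and all libraries were sequenced in one pool as paired reads of 75 nt. The submitters' processing notes name STAR, HTSeq and the mm10 genome build, with versions not given in the sources used here. Whether the counting used strand is also not given, so a gene and an antisense gene that overlaps its exons are treated as possibly sharing reads.

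The authors deposited 1 table of read counts per gene and 1 table of FPKM. The deposited counts are whole numbers that were not normalised. They cover 24060 rows named by gene symbol, of which 2 symbols occur more than once, 0 rows lack a gene name and 2020 rows are 0 in every library. No row carries the name of the construct or of Cre, and no mitochondrially encoded gene is listed. The deposited FPKM values equal the counts divided by a fixed length per gene and by the column total, which was checked on the values, so they add no information beyond the counts. Counted reads per library ranged from 35208460 to 38293012. Symbols were matched to GENCODE M21, whose assembly GRCm38 is the build called mm10: 22806 matched directly and 858 through an older symbol, 23664 in all. Gene coordinates are from this annotation, counted from 1.

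Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr on group, which left 15186 genes, and libraries were scaled by TMM. The quasi-likelihood F test (robust fit) compared bigenic with control libraries, and p was adjusted by Benjamini-Hochberg over all genes tested. Every adjusted p for a single gene comes from this test unless another is named. A gene was called changed at an adjusted p under 0.05, and a second count required more than a 1.5-fold change. Log2 fold changes are bigenic relative to control and carry the standard error of the fit. CPM values use TMM-scaled library sizes and are given as mean ± SD over n = 4 libraries per group. Principal components used log2 CPM (prior count 2) of the 500 most variable genes, and the group difference on each was tested by an exact permutation test, two-sided, over the 35 splits of the 8 libraries into 4 and 4. The smallest p that this design allows is 0.0286.

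Before the data were examined, 38 gene lists were fixed for cell types of the cerebellum and neighbouring tissue, calcium handling, stress, immune and clock genes, metabolism, construct-linked genomic neighbourhoods and RNA quality. Of these, 36 had at least 5 tested members. The mitochondrially encoded list had 0 tested members, and the list of X- and Y-linked sex genes had 1, so neither was tested. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with camera and an estimated correlation, and with fry. The p of camera compares a list with all other genes, whereas fry asks whether the members move on balance one way. List p-values were adjusted over the 36 lists. Members were counted both at an adjusted p over all genes and with p adjusted over the list alone.

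The rule for genes named in the text was also fixed beforehand. It takes the construct-linked genes Atp2b2, Gt(ROSA)26Sor and Aldh1l1, then the 12 higher and the 12 lower genes with the smallest p among genes past the threshold whose groups do not overlap, and up to 4 members with the smallest p from each list. Predicted genes, clones and pseudogenes were passed over. Other genes are named only where the text says that they were chosen after their values were seen.

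The fit was tested on simulated counts drawn for this comparison from the means, dispersions and library sizes of the real libraries, over 15084 genes, of which 200 were changed. It called 58.6% of the genes changed by 1.5-fold and 77% of those changed by 2-fold, and 2.88% of its calls were unchanged genes. These shares hold for that number of changed genes, which is far below the number called in the real libraries. In a simulation in which a list of 30 genes was shifted by 0.5 on the log2 scale, camera called that list and 0 of the 36 unmoved lists. Genes were drawn independently there, whereas list members were correlated in the real data, with an estimate of 0.46 in the granule cell list. The simulation therefore does not test false calls of camera in correlated lists. Pairs of replicates within a group differed by more than sampling noise, with chi-square over degrees of freedom from 11.2 to 70.2, so no library was counted as a repeat of another.

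Alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, Xist as a covariate, 1 surrogate variable (sva 3.50.0), a fit that was not robust, leaving out each of the 8 libraries in turn, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM over 0.5, and on log2(FPKM + 1) with no filter. An offset for GC content and length fitted per library (mgcv 1.9.3), Ttr as a covariate, the fit without control libraries 2 and 3, and scaling by library size alone were added after the data had been seen.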

Results

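RNA was measured in whole cerebellum from 4 bigenic mice and 4 control mice. In the bigenic mice tamoxifen was given to activate Cre in astrocytes and so switch on the CalEx calcium pump. The control mice carry the CalEx allele without Cre and received the same dose of tamoxifen. CalEx is a plasma membrane calcium ATPase that lowers intracellular calcium by exporting it. The comparison of bigenic with control tissue asks how the cerebellar transcriptome differs 5 days after tamoxifen, given to switch on the pump. No row names the construct, so expression of the pump in these libraries could not be checked. Counted reads came to 35679233, 38150087, 35208460 and 36615837 in bigenic libraries 1 to 4 and to 36170554, 37962722, 35619445 and 38293012 in control libraries 1 to 4. The 10 most abundant genes took between 4.02% and 4.65% of the counts in each library.

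Bigenic and control cerebella separated along the main axis of variation. The first principal component of the 500 most variable genes held 69.0% of their variance and placed all 4 bigenic libraries apart from all 4 controls (exact permutation test, two-sided, p = 0.0286, the smallest this design allows). The second component, with 14.2% of the variance, placed control library 4 at -24.3 and the other 7 between -0.86 and 12.3, and did not separate the groups (exact permutation test, two-sided, p = 1). The mean correlation of log2 CPM was 0.9898 between libraries of the same group and 0.970 between libraries of different groups.

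**Figure D1:**
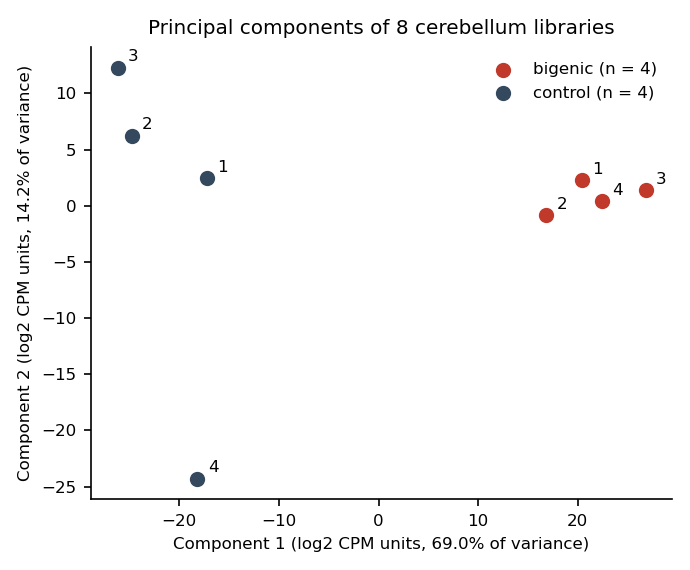
First and second principal components of log2 CPM over the 500 most variable genes, with axes in log2 CPM units, 1 point per library numbered by replicate and colours for the 4 bigenic and 4 control libraries. The groups lie apart on the first component, which holds 69.0% of the variance, and control library 4 lies apart on the second, which holds 14.2%.

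The genes linked to the construct were examined first. Atp2b2, the mouse gene of the pump whose human form CalEx carries (chromosome 6, 113743831 to 114042613, minus strand), was at 577.9, 887.7, 479.9 and 468.6 CPM in bigenic libraries 1 to 4 and at 632.5, 503.1, 444.7 and 442.8 CPM in control libraries 1 to 4. The difference of 0.25 ± 0.20 (SE) on the log2 scale was within the spread between replicates (adjusted p = 0.31). Without bigenic library 2 it was 0.01. Reads from a human coding sequence may not be counted on the mouse gene, so this value does not measure the construct. Gt(ROSA)26Sor, the transcript of the Rosa26 locus (chromosome 6, 113067428 to 113077333, minus strand, with exons antisense to Thumpd3), was at 66.1 ± 11.5 CPM in bigenic and 65.5 ± 2.07 CPM in control libraries (SD, n = 4; adjusted p = 0.93). Aldh1l1, the astrocyte gene whose regulatory sequence drives Cre (chromosome 6, 90486427 to 90600203, plus strand), was higher in bigenic tissue, at 141 ± 7.71 CPM against 101 ± 2.64 CPM in controls (SD, n = 4). Its log2 fold change was 0.48 ± 0.07 (SE; adjusted p = 0.00026). Aldh1l1 exons overlap Gm45901 on the same strand and Gm15756 on the opposite strand, so reads could be shared.

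The difference between bigenic and control cerebellum was broad, with 6734 of the 15186 genes tested, or 44.3%, past the threshold. Of these, 3249 were higher and 3485 lower in bigenic tissue. More than a 1.5-fold change was seen for 2962 genes, 1249 higher and 1713 lower, and more than a 4-fold change for 97 higher and 94 lower genes. The median size of a called change was 0.53 on the log2 scale. The 4 bigenic and the 4 control values did not overlap for 6188 of the genes tested, or 40.7%, against 2.86% by chance. The split depends on the scaling: with library size alone 2423 genes were higher and 4373 lower, and on the deposited FPKM 2250 were higher and 4001 lower with a pseudocount of 1, 2235 and 3980 with a pseudocount of 0.1, and 2227 and 4059 without a filter. Control libraries 2 and 3 hold choroid plexus transcripts, described below with the other cell types, and without them 3394 genes passed the threshold, 1619 higher and 1775 lower. With the level of the choroid plexus gene Ttr as a covariate, 2927 genes passed.

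The 12 higher genes named by the fixed rule rose between 2.29-fold and 9.5-fold. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), rose 9.5-fold, from 5.38 ± 0.694 to 51.1 ± 8.38 CPM (SD, n = 4; log2 fold change 3.25 ± 0.14, SE; adjusted p = 5.3e-07). Cirbp, the cold-inducible RNA-binding protein (chromosome 10, 80165985 to 80172786, plus strand), rose from 68.9 ± 11.4 to 315 ± 45.2 CPM, a log2 fold change of 2.19 ± 0.13 (SE; adjusted p = 2.7e-06). The transcription factor Maff rose by 3.14, the matricellular protein gene Ctgf (Ccn2 in the annotation) by 2.71 and the kinase Map3k6 by 2.70 on the log2 scale. The arrestin family gene Arrdc2 rose by 2.23, the phospholipase Pla2g4e by 2.18, the triglyceride lipase Pnpla2 by 2.08 and the metallothionein Mt1 by 1.88. Etnppl, a phospholyase of astrocytes, rose by 1.596, the proteoglycan Sdc4 by 1.34 and angiotensinogen, Agt, by 1.19. Cdkn1a and Ctgf overlap antisense transcripts and Pla2g4e overlaps a gene on its own strand, so reads could be shared.

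The 12 lower genes fell between 2.2-fold and 8.14-fold. Tnc, which encodes the extracellular matrix protein tenascin C (chromosome 4, 63959785 to 64047015, minus strand, with an antisense transcript over its exons), was at 10.2 ± 3.15 CPM in bigenic and 66.1 ± 6.94 CPM in control tissue (SD, n = 4; log2 fold change -2.70 ± 0.18, SE; adjusted p = 3.6e-06). The zinc finger gene Zfp493 fell by 3.03, the NEDD8 protease Senp8 by 2.28, the matrix protein gene Frem1 by 1.92 and the dynein light chain Dynll1 by 1.38 on the log2 scale. Tek, the endothelial angiopoietin receptor, fell by 1.34, the collagen chaperone Serpinh1 by 1.26, the endoplasmic reticulum protein Pdia4 by 1.25 and the HSP90 co-chaperone Chordc1 by 1.22. Trib2 fell by 1.19, Nrn1, which encodes neuritin and overlaps Fars2 on the opposite strand, by 1.15, and Ciao1 by 1.14.

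**Figure D2:**
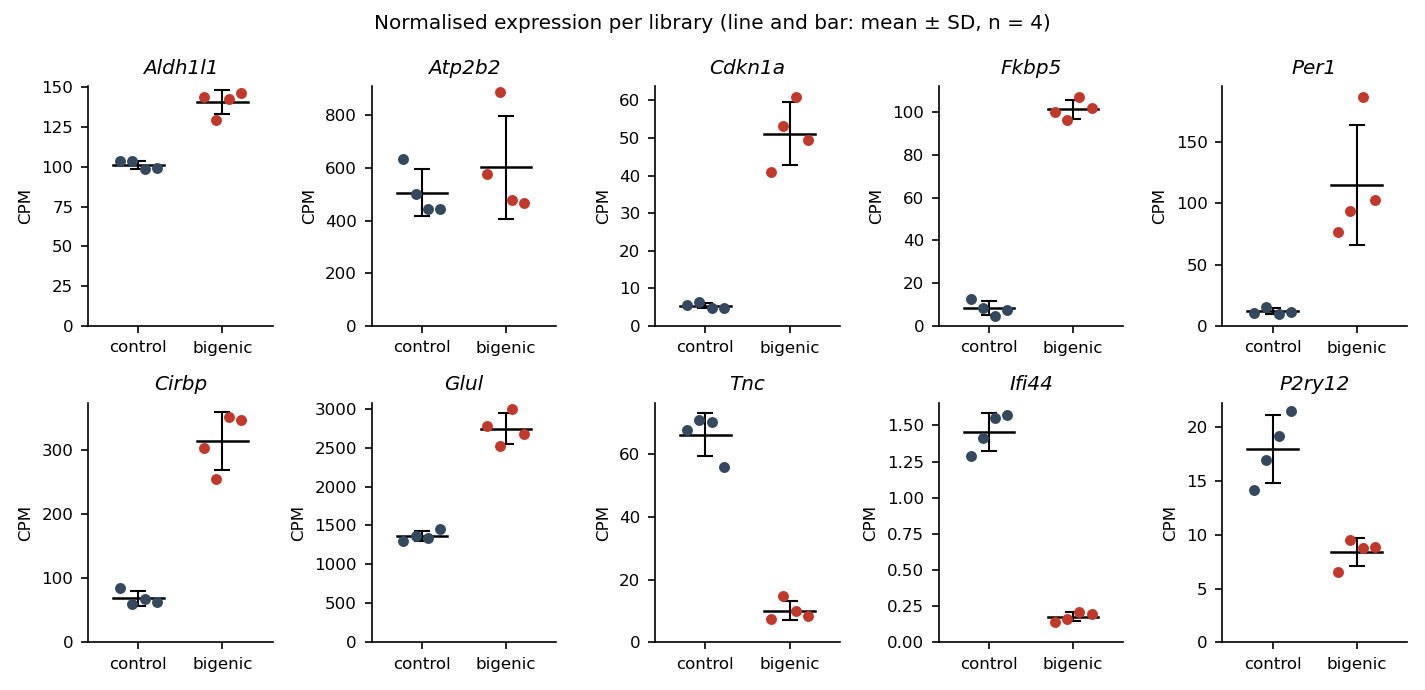
Normalised expression in CPM (linear axes from 0) of 10 genes, 1 point per library, with the mean and SD of the 4 control and 4 bigenic libraries. Cdkn1a, Fkbp5, Per1, Cirbp, Glul and Aldh1l1 are higher and Tnc, Ifi44 and P2ry12 lower in all 4 bigenic libraries, whereas the Atp2b2 values overlap between the groups.

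Glucocorticoid-responsive genes were higher in bigenic cerebellum. Of 30 members tested, 27 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.83. Besides Cdkn1a, Arrdc2, Mt1 and Map3k6, the list holds Fkbp5, a chaperone induced by the glucocorticoid receptor, which rose 12.1-fold from 8.35 ± 3.29 to 101 ± 4.45 CPM (SD, n = 4; log2 fold change 3.601 ± 0.23, SE; adjusted p = 3.6e-06), and Lcn2, lipocalin 2, which rose by 4.02 ± 0.40 (SE) on the log2 scale. Clock genes rose with them: 18 of 22 passed and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.58. Per1, a clock gene that glucocorticoids and cAMP also induce, rose from 11.99 ± 2.61 to 115 ± 49.1 CPM (SD, n = 4), a log2 fold change of 3.26 ± 0.29 (SE; adjusted p = 4.1e-05). Nr1d1, a repressor of the clock, rose by 1.75, Bhlhe40 by 1.41, Tef by 1.30 and Cry2 by 0.99; Nr1d1 shares exonic sequence with the antisense gene Thra. With camera and the preset correlation, adjusted p was 3.4e-19 for the glucocorticoid list and 4.3e-09 for the clock list, and with an estimated correlation adjusted p = 0.051 and adjusted p = 0.33. By the preset test, splits that mix the groups gave a list adjusted p as small as 3.4e-16. That split had 3 bigenic libraries in 1 set and so keeps part of the group difference. With 2 in each set the smallest was 4.2e-10, still below that of the clock list.

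Interferon-responsive and leukocyte genes were lower. In the interferon list 27 of 35 members fell and 1 rose (28 and 1 adjusted over the list alone), with a median log2 fold change of -1.36. Ifi44 was at 0.177 ± 0.0304 CPM in bigenic and 1.46 ± 0.132 CPM in control tissue (SD, n = 4; log2 fold change -3.02 ± 0.25, SE; adjusted p = 1.2e-05), and the guanylate-binding genes Gbp2 and Gbp7 fell by 2.00 and 1.65. The GTPase gene Irgm2 fell by 1.73, and it overlaps Igtp on the same strand. In the leukocyte list 10 of 12 members fell and 0 rose (10 lower and 2 higher adjusted over the list alone), with a median of -0.80, among them the lysozyme gene Lyz2 (-1.01 ± 0.17, SE) and the chemokine receptor gene Ccr2 (-2.44 ± 0.55, SE; call lost with the Ttr covariate, adjusted p = 0.12). Adjusted p by camera was 4.6e-10 for the interferon list and 0.0103 for the leukocyte list, and with an estimated correlation adjusted p = 0.051 and adjusted p = 0.45. Splits that mix the groups reached a smaller list adjusted p by camera with the preset correlation, 3.4e-16 with 3 bigenic libraries in 1 set. With 2 in each set it was 4.2e-10, also below that of both lists. Without control libraries 2 and 3, which hold choroid plexus transcripts, 3 of the leukocyte genes and 24 of the interferon genes fell, with medians of -0.68 and -1.39. On log2(FPKM + 1) the medians were -0.43 and -0.67.

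The microglia list was lower and the cytokine and NF-kB list higher by camera with the preset correlation, with 10 members of each past the threshold in that direction. In the microglia list 10 of 25 members fell and 1 rose, both over all genes and adjusted over the list alone, with a median of -0.19. The purinergic receptors P2ry12 and P2ry13 fell by 1.09 and 1.95 and the fractalkine receptor Cx3cr1 by 1.19 on the log2 scale; P2ry12 lies within Med12l on the opposite strand. In the cytokine and NF-kB list 10 of 20 members rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.40. The chemokine Ccl2 rose by 2.36, the transcription factor Cebpd by 2.17, the NF-kB inhibitor Nfkbia by 1.38 and the interleukin 1 receptor Il1r1 by 1.08. Adjusted p by camera was 0.041 for each of these lists, and with an estimated correlation adjusted p = 0.68 for microglia and adjusted p = 0.45 for cytokines. The microglia list no longer passed without bigenic library 1 (adjusted p = 0.13), control library 2 (0.057), control library 4 (0.061), or control libraries 2 and 3 (0.063), where 5 members fell. Its median was -0.11 without bigenic library 1 and -0.12 without control libraries 2 and 3. The cytokine list did not pass with no filter (adjusted p = 0.079), with the replicate block (0.051) or with the offset for GC content and length (0.066), and its median was 0.19 on log2(FPKM + 1).

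Astrocyte markers were modestly higher on balance, with members in both directions. Of 25 genes tested, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.25. Glutamine synthetase, Glul, rose 2.01-fold from 1367 ± 63.5 to 2742 ± 197 CPM (SD, n = 4; log2 fold change 1.00 ± 0.07, SE; adjusted p = 4.8e-06). The gap junction gene Gjb6 rose by 1.23 and the receptor Fgfr3 by 0.93, whereas Mfge8 fell by 0.67. Adjusted p by camera was 0.0082, and with an estimated correlation adjusted p = 0.45. In the fit without control libraries 2 and 3, 6 astrocyte genes rose and 1 fell, with a median of 0.24. Without bigenic library 3 the median was 0.16, with 9 genes higher and 4 lower, and it was 0.16 with library size alone and 0.15 on log2(FPKM + 1). Gfap, the intermediate filament of astrocytes, was chosen after its values were seen and did not pass, at 142 ± 17.4 CPM in bigenic and 124 ± 20.0 CPM in control tissue (SD, n = 4; adjusted p = 0.20). Without control library 4 its log2 fold change was 0.30 (adjusted p = 0.047). In the reactive astrocyte list 13 of 33 members rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.16), and 9 rose and 7 fell on log2(FPKM + 1). Those that rose included Fkbp5 and Lcn2, and those that fell included Gbp2 and the interferon-induced GTPase Iigp1 (-1.84 ± 0.19, SE).

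Other glial genes moved in both directions. In the astrocyte transport list 9 of 22 genes rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.28); the glucose transporter Slc2a1 rose by 1.15 and the thyroid hormone transporter Slco1c1 fell by 1.63. The list's median was 0.13 and its mean -0.00. The median was 0.041 with library size alone and 0.036 on log2(FPKM + 1), each with 6 genes higher and 6 lower, 0.069 with upper-quartile factors, 0.22 with the offset for GC content and length, 0.054 without bigenic library 3 and 0.20 without control library 4. Of 17 Bergmann glia genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.58). Their median of 0.01 and mean of -0.19 differ in sign, and the median fell below 0 with upper-quartile scaling (-0.05), with library size alone (-0.08) and on log2(FPKM + 1) (-0.09). It was also below 0 without bigenic library 2 (-0.0037), bigenic library 3 (-0.061), bigenic library 4 (-0.046), control library 1 (-0.0082) or control library 4 (-0.032). The fatty acid binding protein Fabp7 fell from 64.3 ± 10.9 to 12.5 ± 4.94 CPM (SD, n = 4; log2 fold change -2.36 ± 0.25, SE; adjusted p = 8.3e-05) and Gdf10 rose by 0.97. Of 20 oligodendrocyte genes 6 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.38), with the galactolipid enzyme Ugt8a down (-1.85 ± 0.20, SE) and transferrin, Trf, down (-0.71 ± 0.08, SE). Of 15 oligodendrocyte precursor genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.82); Gpr17, a receptor of differentiating precursors, fell by 1.91 and Pdgfra rose by 0.40. This list's median was 0.02 and its mean -0.16, and the median was -0.04 with upper-quartile scaling, -0.07 with library size alone, -0.05 on log2(FPKM + 1) and with the offset for GC content and length, -0.12 without bigenic library 2, -0.02 without bigenic library 3, -0.01 without control library 3 and -0.03 without control library 4. The call of Pdgfra was lost with the Ttr covariate (adjusted p = 0.10). Without control libraries 2 and 3, 5 transport genes rose and 3 fell, 2 Bergmann glia genes fell, and 1 oligodendrocyte gene rose and 5 fell.

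Calcium handling genes showed changes of small size. Of 47 genes tested, 17 rose and 5 fell, also adjusted over the list alone, with a median log2 fold change of 0.17. The endoplasmic reticulum calcium sensor Stim1 rose by 0.73 ± 0.07 (SE) and the kinase Camk2g by 0.57 ± 0.08. The Golgi calcium pump Atp2c1 was lower at -0.73 ± 0.08 and the kinase Camk1 at -0.70 ± 0.07 (SE); both overlap a gene on the opposite strand. The list did not pass by camera (adjusted p = 0.082); without control libraries 2 and 3, 8 members rose, and with library size alone 13 rose and 9 fell. The median was 0.083 with library size alone, 0.069 on log2(FPKM + 1) and 0.11 with upper-quartile factors. Among Gq-coupled and other receptors of astrocytes 6 of 28 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.70): the adrenergic receptor Adra1a rose by 1.13, whereas the histamine receptor Hrh1 fell by 0.98 and the endothelin receptor Ednra by 1.16. Of the receptor genes, 1 rose and 6 fell without control libraries 2 and 3, 3 and 9 with library size alone, 4 and 7 with upper-quartile factors, and 3 and 8 on log2(FPKM + 1).

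The heat shock and cholesterol synthesis lists were lower by camera with the preset correlation, with part of their members past the threshold. In the heat shock list 8 of 19 members fell and 1 rose, also adjusted over the list alone, with a median of -0.23; Chordc1 fell by 1.22, Hsph1 by 0.78, Hsf1 by 0.58 and Hspa4l by 0.44. In the cholesterol synthesis list 13 of 25 fell and 3 rose (14 and 3 adjusted over the list alone), with a median of -0.40. The isomerase Ebp fell by 1.09 and Fdps by 0.55, whereas Lss rose by 0.61. Adjusted p by camera was 0.041 for each, and with an estimated correlation adjusted p = 0.45 for heat shock and adjusted p = 0.57 for cholesterol synthesis. Neither list passed without bigenic library 1 (adjusted p = 0.063 for both) or bigenic library 2 (0.10 for both). The heat shock list also failed without control library 2 (0.057) and without control libraries 2 and 3 (0.063), where 4 members fell, and with the offset for GC content and length (0.075), where the median was -0.14 with 6 members lower and 2 higher. The cholesterol list failed without control library 4 (0.061), and without control libraries 2 and 3, 8 members fell. In the unfolded protein response list 12 of 33 fell and 5 rose, also adjusted over the list alone, with Sdf2l1 (-1.79 ± 0.15, SE), Xbp1 (-0.94 ± 0.09) and Pdia6 (-0.80 ± 0.07) among the lower genes; camera gave adjusted p = 0.054.

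Apoptosis and p53 target genes were higher as a list, with 10 of 26 up and 1 down, also adjusted over the list alone, and a median of 0.16. The median was 0.076 without bigenic library 3, 0.071 with library size alone, 0.099 with upper-quartile scaling and 0.080 on log2(FPKM + 1). The BH3-only gene Pmaip1 rose by 1.98, Trp53inp1 by 1.504 and Sesn1 by 0.82, beside Cdkn1a. Ribosomal protein genes were higher by a small amount: 32 of 77 rose and 2 fell, also adjusted over the list alone, with a median of 0.28, Rpl5 at 0.92 ± 0.14 (SE) and Rps14 at 0.63 ± 0.09. These genes have many processed pseudogenes that can take their reads, so their values are uncertain. Adjusted p by camera was 0.018 for apoptosis and 1.1e-05 for ribosomal proteins, and with an estimated correlation adjusted p = 0.45 and adjusted p = 0.68. The count of higher ribosomal protein genes was 10 without control libraries 2 and 3, 17 without bigenic library 4, 21 without control library 3, 18 with library size alone and 48 with the offset for GC content and length, and their median was 0.18 on log2(FPKM + 1). In the cell cycle list 11 of 24 fell and 3 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.20). Its median of -0.54 became 0.01 on log2(FPKM + 1), where 14 members were tested and 3 rose and 3 fell. The median was -0.34 without control library 4, and without control libraries 2 and 3, 5 members fell. Mki67, a marker of dividing cells, fell by 2.81, while Bub1b, Nusap1 and Ccna2 rose by 1.65, 1.83 and 1.48; the last pair overlaps genes on the opposite strand.

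In all, 11 of the 36 lists passed by camera with the preset correlation, 6 higher and 5 lower, 0 with an estimated correlation, and 19 by fry. With the estimated correlation 3 lists had an unadjusted p under 0.05. Over all genes tested, 44.3% were called. The share of members called was close to this in the microglia, apoptosis, ribosomal protein, heat shock and calcium handling lists. Their counts alone therefore show no excess of called members. Camera with the preset correlation gave at least 11 lists in 9 of the 35 splits of the 8 libraries, the real split included. Up to 14 came from another split, with 3 bigenic libraries in 1 set, which keeps part of the group difference. Splits with 2 bigenic libraries in each set gave up to 11. The smallest list adjusted p by this test among the other splits was 3.4e-16, also in a split with 3 bigenic libraries in 1 set. With 2 in each set it was 4.2e-10. Both are below that of every list except the glucocorticoid list. For fry the real split alone reached 19. The medians of the 11 lists kept their sign under every scaling alternative. Some lists share members, so their results are not fully independent. The glucocorticoid list shares 1 gene each with the clock, cytokine and apoptosis lists and 2 with the astrocyte list. Between the astrocyte and astrocyte transport lists 10 genes are shared.

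**Figure D3:**
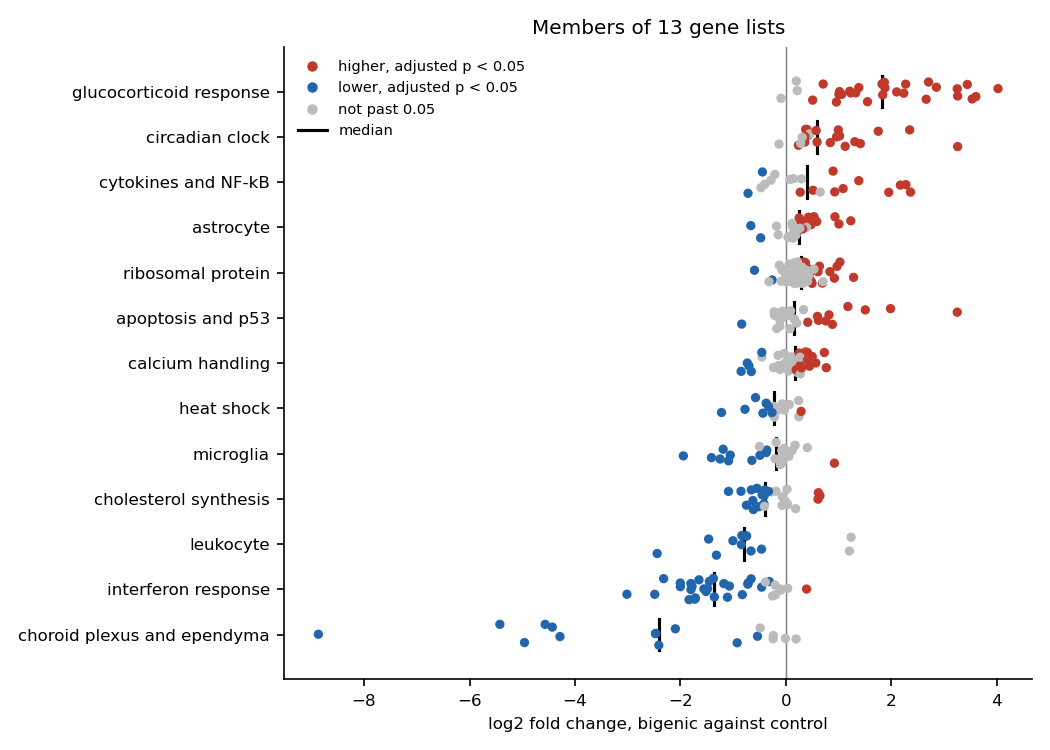
Log2 fold change of bigenic against control for every tested member of 13 gene lists, 1 point per gene, red or blue past an adjusted p of 0.05 and grey otherwise, with a black bar at each list's median. The glucocorticoid list has a median of 1.83 and the interferon list a median of -1.36.

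Genes of the choroid plexus, the secretory tissue inside the brain ventricles, were lower in bigenic libraries but differed most within the controls. The list also holds genes of ciliated ependymal cells, named here after their values were seen: Foxj1, Ccdc153 and Tmem212 did not pass (adjusted p = 0.97, 0.49 and 0.79), and Dynlrb2 was lower (-0.93 ± 0.30, SE; adjusted p = 0.027). Of 17 genes tested 12 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -2.41 (camera adjusted p = 0.054). On log2(FPKM + 1) the median was -0.90, with 6 of 16 genes lower. Prlr was lower by -4.28 ± 0.80 (SE), Kl by -4.96 ± 1.09, Folr1 by -5.42 ± 1.30 and Calml4 by -2.48 ± 0.65. The call of Folr1 was lost with limma-voom (adjusted p = 0.073), and those of Folr1 and Prlr on log2(FPKM + 1) with no filter (0.051 each). With the Ttr covariate the calls of Folr1 (0.67), Calml4 (0.44) and Kl (0.11) were lost, and that of Calml4 also without control libraries 2 and 3 (0.18). The transthyretin gene Ttr, the main transcript of this epithelium and chosen after its values were seen, was at 300.2, 2360, 2961 and 2.76 CPM in control libraries 1 to 4 and between 2.25 and 4.62 CPM in the 4 bigenic libraries. Its difference passed (adjusted p = 0.016), but not with limma-voom (0.098), with the replicate block (0.088), without bigenic library 4 (0.050) or without control libraries 2 and 3 (0.069). Enpp2, also chosen afterwards and also expressed by oligodendrocytes, was at 305.1, 1287, 1680 and 248.5 CPM in control libraries 1 to 4 and between 114 and 178 CPM in bigenic libraries (adjusted p = 0.018). This call was lost with the replicate block (0.073), without bigenic library 1 (0.053) and with the Ttr covariate (0.37). Without control libraries 2 and 3, 3 choroid plexus genes fell and 1 rose, and 6, 6, 7 and 6 fell without bigenic library 1, 2, 3 or 4 and 7 without control library 2.

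Single libraries also differed in other genes. Counts from the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in control library 3 alone, at 207, 105, 63.8 and 38.6 CPM, and were 0 in the other 7 libraries. Xist, expressed from the inactive X chromosome, was at 0.083 CPM in control library 3 and between 132 and 142 CPM in the other controls. In bigenic libraries it was between 163 and 291 CPM, so each bigenic value was above each control value (adjusted p = 0.53, or 0.031 without control library 3). By these genes control library 3 came from a male and the other 7 libraries from females, so sex was not balanced between the groups. Among the 15186 genes tested, which leave out these Y-linked genes, 25 were more than 4-fold above every other library in control library 4 (on log2 CPM with a prior count of 2), against 0 such genes in each of the other 7. Chosen after their values were seen, Lhx9 was at 12.3 CPM there and between 0.139 and 0.479 CPM elsewhere, Nrgn at 14.9 CPM, Tac1 at 9.44 CPM and the glutamate transporter Slc17a6 at 110 CPM.

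**Figure D4:**
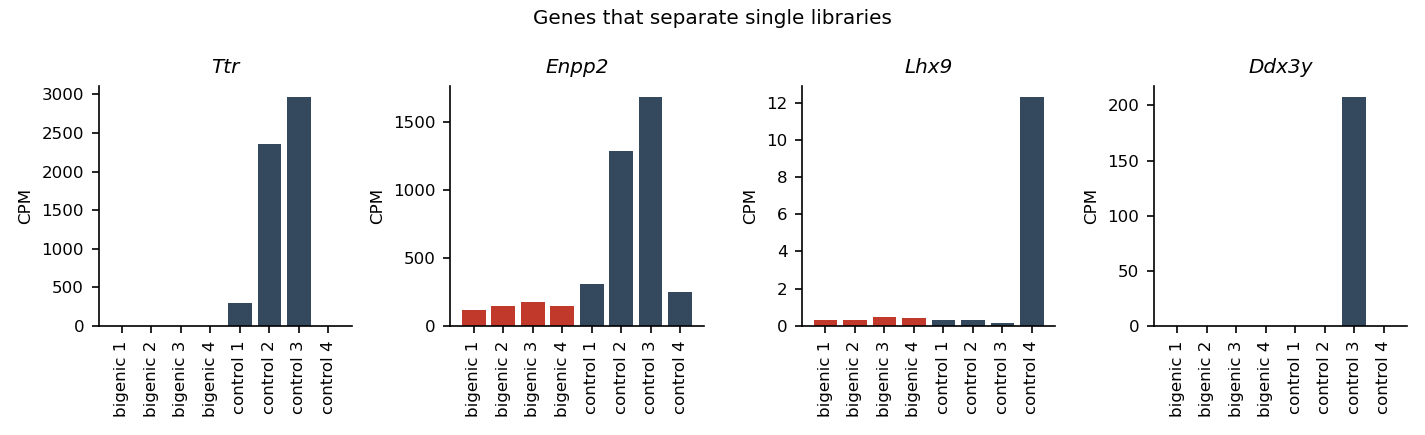
CPM (linear axes from 0) of Ttr, Enpp2, Lhx9 and Ddx3y in each of the 8 libraries, 1 bar per library, with bigenic libraries in red and control libraries in dark blue. Ttr and Enpp2 are highest in control libraries 2 and 3, Lhx9 in control library 4 and Ddx3y in control library 3.

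Genes next to Aldh1l1 were examined because Cre is driven by its regulatory sequence. Of 7 genes tested in this list, which includes Aldh1l1 itself, 4 rose and 0 fell (4 and 1 adjusted over the list alone). Camera gave adjusted p = 0.053. Over all genes tested 44.3% were called, so this count alone does not set the neighbourhood apart. Klf15, a transcription factor that is also in the glucocorticoid list (chromosome 6, 90462576 to 90475238, plus strand), rose from 21.2 ± 3.72 to 74.9 ± 8.31 CPM (SD, n = 4; log2 fold change 1.82 ± 0.13, SE; adjusted p = 3.8e-06). The magnesium transporter gene Slc41a3 (chromosome 6, 90604725 to 90646412, plus strand) rose by 1.18 ± 0.10 (SE; adjusted p = 1.1e-05). Txnrd3 rose by 0.43 ± 0.13 (adjusted p = 0.020). This call was lost at similar folds without bigenic library 4 (0.42, adjusted p = 0.052), without control libraries 2 and 3 (0.45, adjusted p = 0.11) and with the Ttr covariate (0.46, adjusted p = 0.15). It was also lost on log2(FPKM + 1) and log2(FPKM + 0.1), at 0.25 and 0.32 (adjusted p = 0.053 each). Among genes near Rosa26 and Atp2b2 on the same chromosome, 7 of 16 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.19). Their median was 0.18. It was -0.03 on log2(FPKM + 1), 0.094 with library size alone and 0.29 without control library 4. Without control libraries 2 and 3, 3 rose.

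**Figure D5:**
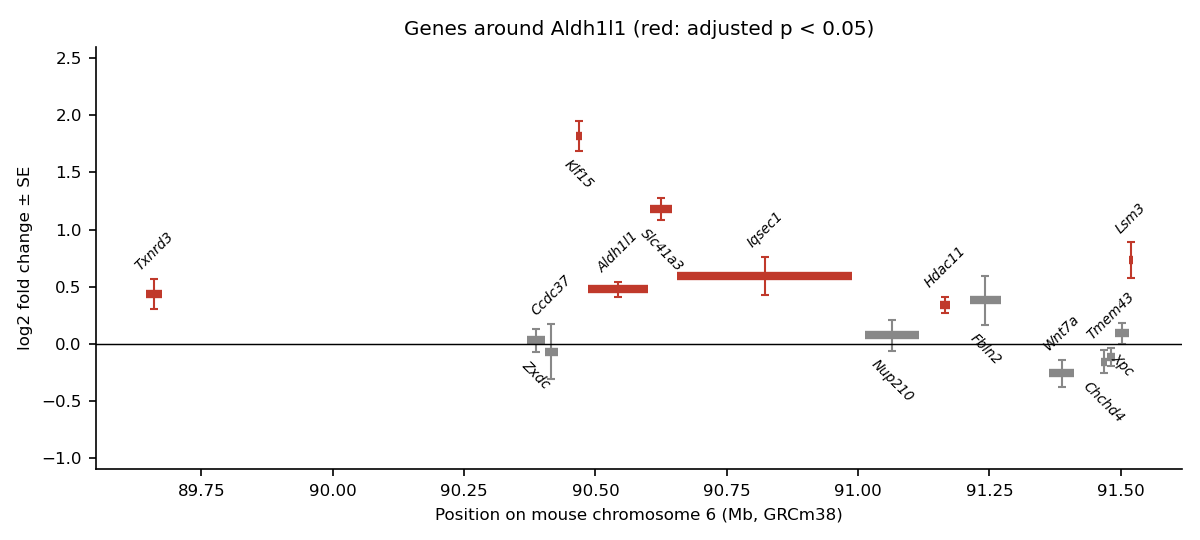
Log2 fold change (± SE) of tested genes within 1 Mb of Aldh1l1 against position on mouse chromosome 6 in Mb (GRCm38), with the thick line spanning each gene and red for an adjusted p under 0.05. Klf15 at 1.82 and Slc41a3 at 1.18, on either side of Aldh1l1 at 0.48, have the highest values.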

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

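All tests of explanations in this part were chosen after the results they bear on had been seen. The main counts were set beside those of all 35 splits of the 8 libraries into 4 and 4. The count of 6734 genes was reached by 1 split, the real one, and the highest other split gave 0. For genes over 1.5-fold the real split gave 2962, again reached by 1 split, and the highest other gave 0. Every other split mixes bigenic and control libraries, so a group difference adds to the spread within its sets and keeps its count low. Being 1 of 35 splits is the smallest share this design allows (0.0286), so these counts alone do not exclude chance. For lists by camera with the preset correlation, 9 splits reached the 11 lists of the real split, and the highest other gave 14. Splits with 14 lists had 3 bigenic libraries in 1 set, so they keep part of the group difference. Splits with 2 bigenic libraries in each set balance the groups, and they reached up to 11. Chance therefore cannot be excluded for that count. By fry the real split gave 19 lists, 1 split reached this and the highest other gave 2, with the same limits as for the gene counts.

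Choroid plexus genes were lower in bigenic libraries, and choroid plexus tissue in part of the control libraries is a candidate explanation. The 12 called members had a median range of 3.86 (log2) within the 4 controls and 0.958 within the 4 bigenic libraries, with Ttr between 2.76 and 2961 CPM in controls. The tables argue against the same tissue as the source of most other called genes: over 6722 of these the fold change without control libraries 2 and 3 was a median of 0.974 of that with all 8 (quartiles 0.897 and 1.05), while the choroid plexus median went from -2.41 to -0.49. This does not cover every gene, because control library 1, with Ttr at 300.2 CPM, stayed in that fit, where Ttr was still at -5.65 (adjusted p = 0.069), and the meningeal median went from -0.38 to -0.06. Whether a difference between the groups comes on top cannot be told apart, since 4 of the 12 members do not overlap between the groups, and the numbers of libraries are small.

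Glucocorticoid and clock genes were higher in bigenic libraries. A different time of day of collection was weighed as a shift along a single daily cycle. It was taken to lower Arntl, Npas2, Clock and Cry1 by about the 0.58 that the clock list rose. Their median was instead 0.40 with an SD of 0.277. Arntl was at 0.37, Npas2 at 0.45 (adjusted p = 0.077), Cry1 at 0.43 and Clock at -0.13 (adjusted p = 0.23). Without 1 library Clock was at -0.19 at the lowest, and Cry1 lost its call under most alternatives. Arntl lost its call on FPKM (0.055 to 0.090), with the Ttr covariate (0.14) and without control libraries 2 and 3 (0.096). With that covariate and without those libraries its log2 fold change was 0.41 and 0.39. The size of the fall was an assumption, since these genes need not swing equally. The values speak against a fall of that size but do not exclude another collection time. A larger share of astrocytes would raise the astrocyte list as much as the glucocorticoid list, whose median was 1.83, but the astrocyte median was 0.25 with an SD of 0.416. With an offset for GC content and length the glucocorticoid median was 1.86, which argues against that bias. What stays open is a difference between groups in collection time, or in handling or stress before collection, of which the labels say nothing. An effect of the pump or of Cre, which the design does not separate, also stays open. Handling, stress, the pump and Cre were not tested, and these remain hypotheses.

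Cirbp and Rbm3, a pair of cold-inducible RNA-binding proteins, were higher in bigenic libraries; Rbm3 was chosen after its values were seen and rose by 1.73 ± 0.12 (SE). A lower temperature of the tissue before collection could raise both and lower heat shock genes, and the heat shock list had a median of -0.23 (fry adjusted p = 0.0023, with 8 of 19 genes lower and 1 higher). This support is weak: by camera with an estimated correlation adjusted p = 0.45, the preset call was lost on leaving out bigenic library 1, bigenic library 2 or control library 2, and with the offset for GC content and length the median was -0.14 with 6 lower and 2 higher. With that offset the mean log2 fold change of Cirbp and Rbm3 was 2.03 against 1.96 without, which argues against that bias. No temperature is given in the labels, and an effect of the pump or of Cre also stays open.

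Single libraries far from the other 3 of their group were found for 26 of 414 groups of 4 values, where chance gives about 1 in 20. The count is close to that rate, so many of these could be chance. It also includes Lhx9, Tac1 and Nrgn, which were chosen after 1 library was seen to stand apart. In control library 3 these were Ddx3y at 207, Uty at 105, Kdm5d at 63.8 and Eif2s3y at 38.6 CPM, Xist at 0.083, Sox10 at 16.0, Lypd6 at 40.6 and Pdia6 at 114 CPM, and the mean of the oligodendrocyte precursor list at 4.21 (log2 CPM). In control library 4 they were Lhx9 at 12.3, Tac1 at 9.44, Nrgn at 14.9 and Atp5l at 3.61 CPM. In control library 1 they were Dynll1 at 103, Fabp7 at 47.9, Lcn2 at 0.134, Tef at 344, Brpf1 at 72.5, Hist1h2bc at 34.4 and Atp5sl at 57.0 CPM. In control library 2, Trf stood at 873 CPM. In bigenic library 3 they were Map3k6 at 11.8, Sycp1 at 91.6 and Ndufc1 at 25.0 CPM, in bigenic library 2 Xist at 291 CPM, and in bigenic library 1 the mean of the list of genes near Rosa26 and Atp2b2 at 5.24 (log2 CPM).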

How the results depend on the processing

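The GC and length offset, the Ttr covariate, the fit without control libraries 2 and 3 and scaling by library size alone were chosen after the data had been seen. Under the alternatives on counts fixed beforehand the number of called genes ran from 5281 to 8304, against 6734, with 0 calls changing sign; the offset gave 7473 genes, with 2 changing sign. The Ttr covariate gave 2927 genes (1269 higher, 1658 lower) and kept 40.5% of the calls, with 17 changing sign, and the fit without control libraries 2 and 3 gave 3394 (1619 higher, 1775 lower) and kept 48.9%, with 1 changing sign. The second has fewer samples. In the first, Ttr was between 2.25 and 4.62 CPM in bigenic libraries and between 300 and 2961 CPM in control libraries 1 to 3. The covariate thus partly follows the group, and a call lost with it does not show a choroid plexus origin. The cause of the drop with it was not tested. Genes over 1.5-fold numbered 1645 on log2(FPKM + 1) and 1620 with no filter, where the pseudocount shrinks the folds of low genes. Lists past the threshold numbered 0 with an estimated correlation and 19 by fry, and from 8 to 16 on leaving out 1 library. Of the 11 lists, the cytokine list lost its call with no filter (adjusted p = 0.079) and with the replicate block (0.051), and the cytokine and heat shock lists lost theirs with the offset (0.066 and 0.075); over all alternatives adjusted p ran from 0.0012 to 0.45 for the cytokine and from 0.0023 to 0.45 for the heat shock list.

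Of the named genes, Gt(ROSA)26Sor, never past the threshold, changed sign: -0.046 with upper-quartile factors, -0.0026 with limma-voom, -0.0064 with no filter, -0.00048 with the replicate block, -0.083 on log2(FPKM + 1) with and without a filter, -0.086 on log2(FPKM + 0.1), -0.073 with library size alone, and from -0.113 to 0.092 on leaving out 1 library. With the Ttr covariate Gfap was at -0.020. On leaving out 1 library Lhx9 ran from -3.46 to 0.59, Tac1 from -2.31 to 0.97 and Slc17a6 from -1.51 to 0.31. The upper values came without control library 4. There Lhx9 was at 12.3 CPM against 0.139 to 0.322 CPM in the other controls, and Tac1 at 9.44 against 0.256 to 0.499 CPM. The difference of Lhx9 and Tac1 thus rests on that library. Why it stands apart was not tested. The Ttr covariate ended the call of 28 of 165 named genes and the fit without control libraries 2 and 3 that of 24 of 166. Of the alternatives fixed beforehand, log2(FPKM + 1) with no filter ended 12 of 166, each filtered FPKM fit 7 of 156, upper-quartile factors and the replicate block 4 each, limma-voom 3, no filter 2, the Xist covariate 2, the surrogate variable 1, and leaving out 1 library up to 5. Same-numbered libraries deviated together with correlations of 0.33, 0.02, 0.17 and 0.06, all positive but mostly small. Of the 4 bigenic libraries, 3 correlated best with the control of their own number, as a hint from the data only. The replicate block gave 7443 genes. These values do not decide whether the numbers pair the samples, and the labels state no pairing. By the mouse tags in the labels, bigenic library 1 and control library 1 came from consecutively numbered mice, unlike the other same-numbered libraries. Whether any mice shared a litter or cohort is not given and was not tested. In a simulation with 200 of 15084 genes changed, 58.6% of the genes changed by 1.5-fold were called. In the real comparison 44.3% of genes were called, which moves the adjusted threshold, so the simulated share does not carry over to it.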

Other observations

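Neuronal markers of the cerebellum differed little in size between bigenic and control tissue. Of 24 granule cell genes 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.57). Gabrd, a subunit of extrasynaptic GABA receptors, rose by 0.45 ± 0.09 (SE) and Cbln3 by 0.39 ± 0.08, while Neurod1 was lower at -0.33 ± 0.07, a call lost with the Ttr covariate (adjusted p = 0.096) and without control libraries 2 and 3 (0.076). The granule cell median was 0.07, and it was -0.02 with library size alone (6 higher, 6 lower), -0.04 on log2(FPKM + 1) (6 higher, 7 lower), -0.01 without bigenic library 2 and -0.01 without control library 4. Of 25 Purkinje cell genes 5 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.16). Pvalb was at 0.27 ± 0.07 (SE), but its call was lost on log2(FPKM + 1) with no filter (0.18, adjusted p = 0.23). The call was also lost, at folds that did not shrink, without control libraries 2 and 3 (0.30, adjusted p = 0.054) and with the Ttr covariate (0.29, adjusted p = 0.080). The Purkinje counts depended on the scaling, with 1 higher and 2 lower with library size alone, 1 and 1 on log2(FPKM + 1) and 2 and 1 with upper-quartile factors. Of 20 interneuron genes 4 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.37), with Prkcd at 0.55 ± 0.08 (SE). With upper-quartile factors, with library size alone and on log2(FPKM + 1), 3 interneuron genes rose and 5 fell. Of 6 brainstem and midbrain genes tested 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.45), and 0 rose without control libraries 2 and 3. In the vascular list 4 of 24 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.58), with the endothelial receptors Kdr and Tek lower by -0.99 ± 0.11 and -1.34 ± 0.09 (SE) and the glucose transporter Slc2a1 higher by 1.15 ± 0.11. Of 17 meningeal fibroblast genes 1 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.11); the collagens Col3a1 and Col1a1 fell by 1.28 and 1.36. Of 5 blood cell genes 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.17). Only 1 blood cell gene fell without control libraries 2 and 3 and with the Ttr covariate, with medians of -0.67 and -0.65 against -0.61. Without control libraries 2 and 3, which hold choroid plexus transcripts, 4 granule cell and 0 Purkinje cell genes rose, 1 vascular gene rose and 2 meningeal genes fell. The meningeal median moved from -0.38 to -0.06 there and to -0.02 with Ttr as a covariate. In the Purkinje list 1 gene rose without control library 2 and 2 without control library 4, 5 interneuron genes fell without bigenic library 2, and 4 meningeal genes fell without control library 2.

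Activity and metabolic genes moved both ways. Of 27 immediate early genes 10 rose and 7 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.59). Their median of -0.06 and mean of 0.07 differ in sign. The median was -0.12 with upper-quartile factors, -0.15 with library size alone and 0.0068 with the offset for GC content and length. It was -0.19 without bigenic library 3 and -0.015 without bigenic library 1. Egr1 rose by 1.597 ± 0.22 (SE) and Cyr61, annotated as Ccn1, by 2.61 ± 0.38, beside Maff. Of 17 targets of CREB and calcineurin 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.99); Per1 and Ppargc1a rose by 3.26 and 0.59, and Crem and Bdnf fell by 0.70 and 0.71. The call of Bdnf was lost with the Ttr covariate (adjusted p = 0.10) and without control libraries 2 and 3 (0.077). For glycolysis 7 of 28 rose and 7 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.96): Pdk4, which restrains pyruvate oxidation, rose by 1.06, and lactate dehydrogenase, Ldha, fell by 0.75. With upper-quartile factors and with library size alone, 6 glycolysis genes rose and 10 fell. For nuclear genes of oxidative phosphorylation 11 of 77 rose and 9 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.57). Their median of 0.07 was -0.02 with library size alone and on log2(FPKM + 1), and ran from 0.022 to 0.10 on leaving out 1 library. The counts depended on the scaling. The balance turned to 6 higher and 20 lower with library size alone, 7 and 18 with upper-quartile factors and 7 and 20 on log2(FPKM + 1). It kept its direction with the offset for GC content and length, where 26 rose and 8 fell. Of 31 matrix and synaptogenic genes 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.093); Mertk, a phagocytic receptor, rose by 1.32, Timp3 by 0.98 and Sparc by 0.65, against the fall of Tnc. Of 14 structural RNA and histone genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.54), and with the offset for GC content and length 3 rose and 3 fell. Without control libraries 2 and 3, 4 immediate early genes rose and 1 fell, 3 glycolysis genes rose and 2 fell, and 3 oxidative phosphorylation genes rose and 2 fell. The count of higher oxidative phosphorylation genes was 22 without bigenic library 2, 6 without bigenic library 4 or control library 2 and 7 without control library 3, and 7 matrix genes rose and 7 fell without bigenic library 2.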
